A study of Mus musculus with 8 samples.

How the data were processed

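Total RNA of regenerating mouse liver was extracted with TRIzol and purification columns and made into libraries with a NuGEN Ovation RNA-seq kit, per the labels' protocols. The deposited values are raw read counts, which the authors made with HISAT2 2.1.0 and HTSeq 0.6.1, and the genome builds named are GRCm38 and mm10, per the submitters' processing notes. The annotation version and the strand setting of the counting are not given in the sources used here, so counts of overlapping and antisense genes are uncertain. Each of the 8 libraries has its own column of 33628 features and 5 summary lines for reads that were not counted. The deposited features are transcripts, of which 25969 (77.22%) could be given a gene name from RefSeq and GENCODE tables, for 20341 genes. The 7659 unnamed features, of which 6007 carry numbers in place of names, stayed in the tests under their identifiers. They held 6.12% to 8.298% of assigned counts per library and are counted but not named. Counts of the transcripts of a gene were added up, a choice made after the files were seen, since 3562 genes have several of them. The median of the mean count was 7.0 for these genes and 84.19 for genes with 1 transcript. The handling of reads shared by transcripts is not stated, so these genes may be measured less completely.

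Depth was 7624975 to 12136916 assigned counts per library, which is 27.4% to 33.1% of the reads. Reads outside features were 21.2% to 27.4%, ambiguous reads 6.35% to 7.31%, reads not aligned 6.86% to 9.56% and reads aligned more than once 26.1% to 30.4%. No 2 libraries were near copies of each other, with a smallest chi-square per degree of freedom of 14.15 between pairs.

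Groups were taken from the labels: 4 GSK2801 libraries and 4 GSK8573 libraries, the inactive control. The comparison is GSK2801 minus GSK8573 throughout. Genes were filtered with edgeR's filterByExpr, scaled by TMM factors and tested with edgeR's robust quasi-likelihood F test, two-sided, with group as the only term (R 4.3.3, edgeR 4.0.16). Genes with a Benjamini-Hochberg adjusted p under 0.05 are called, and rose, fell or changed refers to these. Standard errors and 95% confidence intervals were derived from the log2 fold change and the F statistic of the same fit, whose biological coefficient of variation was 0.382. They are approximate, above all for genes with few counts in a group. Of the called genes 36 are among the 913 tested genes with several transcripts and 25 among the 738 tested features without a name. CPM values are scaled by TMM factors, and log2 CPM uses a prior count of 2. For a gene with no count in a group, the fold is given against a floor of 3 counts over the group, and for a gene with 1 to 3 counts the ratio of summed counts is given with an exact counting interval.

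Before the data were examined, the tests, the threshold, the alternatives, 55 gene lists with 1719 genes (1682 present in the files) and the rule for naming genes were fixed. The rule names Baz2a and Baz2b; the 10 genes with the largest increase and the 10 with the largest decrease among called genes with a mean CPM of 1 or more and no overlap between the groups (402 and 243 genes qualified); and in each list up to 4 called members with the smallest p, or at most 2 members with the smallest p where none was called. Some genes that the rule names are not reported here. Lists with 5 or more measured genes, 50 of the 55, were tested with limma camera (limma 3.58.1, preset inter-gene correlation 0.01), two-sided, with adjustment over the 50 lists. List scores are the mean log2 CPM of the members and were compared with exact two-sided permutation tests over the 70 assignments of the libraries, with intervals from inverting the test; adjusted permutation p-values are over the 50 lists. Counts adjusted over the list alone use only the p-values of its members.

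Alternatives were RLE and upper-quartile scaling, removal of the 20 most abundant genes, no count filter, a mean CPM of 1 or more as the filter, the replicate number as a block, offsets that remove each library's trend of log counts on GC content and length (natural splines with 4 degrees of freedom, known for 92.9% of tested genes), the block with these offsets, each library left out in turn, a TREAT test against 1.2-fold, DESeq2 1.42.0, limma-voom with sample quality weights, an estimated inter-gene correlation, and fry. Scaling by library totals alone, leaving out GSK8573 libraries 1 and 4, only genes with 1 transcript, and transcripts as deposited were added after the data were seen. The GC and length offsets include the mean level of each library's trend, so they also bring the mean log counts of the libraries to the same level. Where libraries were left out, genes were filtered anew, so the tested members of a list can differ from those of the main test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

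The pipeline was tested on simulated data with 10622 genes, of which 100 changed 2-fold and 100 changed 4-fold. It called 31% of the former and 67% of the latter with no wrong sign, 9.26% of its 108 calls were false, above the 5% aimed at, and 0 of 50 lists without change were called. The simulated genes were drawn independently of each other, with the same spread in both groups and no library that stands apart. The simulation therefore does not show how often camera calls unchanged lists whose genes move together. Nor does it show how many changes are found, or falsely called, when the groups differ in spread as here. Summary lines for uncounted reads were left out of library sizes and tests. None of the 13 mitochondrially encoded genes was matched by name to a feature, so their share was not computed.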

Results

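RNA was sequenced from regenerating livers of wild-type B6 mice, collected 48 h after surgery that removed 70% of the liver. The mice received 30 mg/kg per day of GSK2801, an inhibitor of the bromodomains of the chromatin proteins BAZ2A and BAZ2B, or the same dose of GSK8573, its inactive control compound, from 2 days before surgery until collection. Each compound had 4 libraries, and animals given vehicle alone were not analysed here. GSK8573 libraries 1 to 4 held 10807684, 8489873, 8746381 and 12136916 counts assigned to genes. GSK2801 libraries 1 to 4 held 7624975, 8655737, 7814046 and 9549728. The labels do not say whether the libraries of a group came from separate animals, so every p-value measures the spread between these samples. Intervals and floors based on counts cover counting error only, and the labels mention no molecular identifiers.

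The comparison of GSK2801 with GSK8573 addresses which transcripts differ in regenerating liver when the BAZ2 bromodomains are inhibited. Of 56 tested genes of mitosis 37 rose with GSK2801, and of 36 acute phase genes 20 fell. Among targets of the nuclear receptors CAR and PXR 10 rose and 3 fell, among NRF2 targets 6 rose and 1 fell, and of 39 PPAR-alpha targets and fatty acid oxidation genes 12 fell. None of these 5 lists was called with an estimated inter-gene correlation (limma camera, adjusted p from 0.311 to 0.412). For example, Anln, which encodes the cytokinesis protein anillin, had 6.79 ± 3.65 CPM (normalised read count, scaled by library size; SD, n = 4) with GSK8573 and 67.1 ± 13.02 with GSK2801. Hp, which encodes the plasma protein haptoglobin, had 30150 ± 10640 CPM with GSK8573 and 9342 ± 1117 with GSK2801.

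Of 10622 genes tested, 424 rose and 286 fell with GSK2801 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 2240 had an unadjusted p under 0.05. The 4 values of the groups did not overlap in 1687 tested genes (15.88%), against 2.86% by chance, and 676 of these are among the 710 that changed, which were selected for a difference between the same groups. Without GSK8573 libraries 1 and 4, which stood apart from the rest, 696 genes changed, 459 of them among the 710. Leaving out GSK8573 library 3 gave 430 genes, and leaving out GSK2801 library 1, 2, 3 or 4 gave 281, 261, 441 or 356. Scaling by library totals alone put the median log2 fold change of all genes at 0.34 and gave 1099 higher and 92 lower genes. Offsets for GC content and gene length, which also bring the mean log counts of the libraries to the same level, put it at -0.14. They gave 356 higher and 604 lower genes.

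The BAZ2 genes themselves did not pass the test. Baz2a, on chromosome 10 from 128091370 to 128129303 (GRCm38), had 88.1 ± 13.9 CPM with GSK8573 and 89.6 ± 9.81 with GSK2801, a log2 fold change of 0.02 with a 95% confidence interval of -0.30 to 0.35 (adjusted p = 0.957). Baz2b, on chromosome 2 from 59899363 to 60209913, had 73.2 ± 4.64 CPM with GSK8573 and 52.5 ± 5.85 with GSK2801, a log2 fold change of -0.48 with an interval of -0.78 to -0.18 (adjusted p = 0.0613). Over 22 alternative settings the adjusted p of Baz2b ranged from 0.0199 to 0.626, and it missed the threshold in 19. Among 12 tested BAZ2 and ISWI remodeler genes, Rbbp7, a histone-binding subunit shared by several complexes, rose (log2 fold change 0.64, SE 0.14), none fell and 11 did not pass. Adjusted over the list alone, 1 rose and 1 fell, Baz2b; without GSK2801 library 3 or 4 the count of genes that rose was 0, as it was without GSK8573 libraries 1 and 4 and with GC and length offsets, where 1 fell; upper-quartile scaling gave 1 that rose and 1 that fell. Among 25 bromodomain genes, Brd8 (0.59, SE 0.14) and Atad2 (1.603, SE 0.40) rose and 23 did not pass, with 2 adjusted over the list alone. The bromodomain count was 0 without GSK8573 library 3 or GSK2801 library 1, 2 or 3, and 1 without GSK8573 library 4 or GSK2801 library 4 or with GC and length offsets, and 5 with library totals alone. The remodelers had a mean of 0.02, a median of -0.04 and a mean of -0.02 with upper-quartile scaling. The bromodomain genes had a mean of 0.09, which turned to -0.01 with GC and length offsets. Neither list was called (adjusted p = 0.9773 and 0.9747, limma camera).

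The genes with the largest increases included 5 with no count in any GSK8573 library, for which a fold is a lower bound against a floor of 3 counts over the group. Chrna4, which encodes a nicotinic acetylcholine receptor subunit, was at least 167-fold higher, Clec2h at least 49.8-fold, Ces1a, a carboxylesterase, at least 41.3-fold, Cfap44 at least 25.0-fold and Cenps, a centromere protein, at least 24.4-fold higher. Arhgef39 had 2 counts over the GSK8573 libraries and 557 over the GSK2801 libraries, a ratio of 261.5 (95% counting interval 72.1 to 2164). Gipc2 had 1 and 121 counts, a ratio of 113.6 (20.01 to 4524). Ska3, a kinetochore gene, rose by a log2 fold change of 6.61 (SE 0.80), Rasgrf2 by 6.50 (SE 0.70) and Serpinb8 by 6.29 (SE 0.74). Without GSK8573 library 1 the GSK8573 mean of Ska3 goes from 0.1549 to 0 CPM and that of Gipc2 to 0. Without GSK8573 library 2 that of Arhgef39 goes to 0, that of Rasgrf2 from 0.1256 to 0.08317 and that of Serpinb8 from 0.2427 to 0.02869, so these folds rest on few counts. Without GSK2801 library 1 the GSK2801 mean of Gipc2 goes from 3.288 to 1.839 and the gene did not pass (adjusted p = 0.0813). GSK2801 library 1 held 30.89 CPM of Chrna4 and 9.748 of Clec2h, and without it the bounds are 109.4-fold and 30.67-fold; without GSK2801 library 4 that of Ces1a is 27.3-fold. Cenps missed the threshold in 8 of 22 alternatives, Cfap44 in 6, Ces1a in 3, Chrna4 in 2 and Clec2h and Gipc2 in 1 each, with adjusted p-values up to 0.1208, 0.1171, 0.06409, 0.2258, 0.05425 and 0.08132. Without GSK2801 library 1, 2, 3 or 4 neither Cenps nor Cfap44 passed, and Cenps did not without GSK8573 library 3. Clec2h did not pass without GSK2801 library 1, nor Ces1a without GSK2801 library 4. Reads of Ces1a can also match its close paralogs, so its level is less certain than that of a gene without near copies.

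The largest decreases were in Cntnap1 (log2 fold change -4.37, SE 0.57), Irak3, a regulator of interleukin-1 receptor signalling (-3.88, SE 0.93), and Igdcc4 (-3.52, SE 0.73). Mat1a, the methionine adenosyltransferase of adult liver, had 6893 ± 3665 CPM with GSK8573 and 1181 ± 449 with GSK2801 (-2.55, SE 0.41). Mfsd2a, a lysolipid transporter, Csad, an enzyme of taurine synthesis, and Lcn2, lipocalin 2, fell with log2 fold changes of -2.38, -2.37 and -2.32. Socs3, a feedback inhibitor of cytokine signalling, Apoa5, a regulator of plasma triglyceride, and Irs2, an adaptor of the insulin receptor, fell with values of -2.29, -2.24 and -2.24. GSK8573 library 1 held 261.4 CPM of Csad, 46.83 of Irak3 and 25010 of Lcn2, against 95.7 to 116.2, 3.539 to 11.98 and 5032 to 9169 in the other 3. Without it the log2 fold changes of Irak3 and Lcn2 were -2.68 and -1.69, and without GSK2801 library 3 that of Igdcc4 was -4.10. Irak3 and Csad each missed the threshold in 10 of 22 alternatives, with adjusted p-values up to 0.140 and 0.153; Igdcc4, Mfsd2a and Lcn2 did in 5 each and Irs2 in 4.

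**Figure D1:**
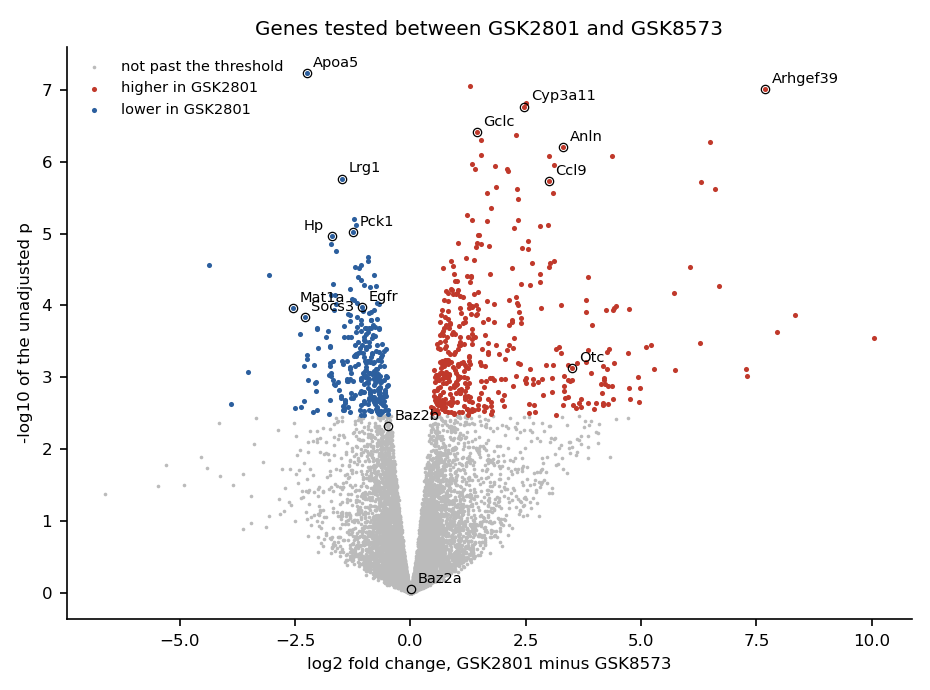
Each point is 1 tested gene, with its log2 fold change (GSK2801 minus GSK8573) on the horizontal axis and minus log10 of its unadjusted p on the vertical axis; coloured points are the 424 genes that rose and the 286 that fell. Scaling by library totals alone gave 1099 higher and 92 lower genes, so the balance between the sides depends on the scaling.

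The 50 lists of genes with 5 or more measured members were tested with limma camera at a preset inter-gene correlation of 0.01. Of these lists, 7 were called higher and 6 lower. With the correlation estimated for each list, 0 of the 50 lists were called, and 6 had an unadjusted p under 0.05. An exact permutation test of list scores called 0 lists after adjustment, with 13 at the smallest p that 4 against 4 libraries allow (0.02857; adjusted p = 0.110). Fry called 12 lists by its PValue, which tests whether the genes of a list move, on balance, one way. Its PValue.Mixed, which tests whether they change in either direction, called 47, and neither compares a list with other genes. Other divisions of the same 8 libraries into 4 and 4 gave up to 19 list calls and at most 1 gene call.

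Of 56 tested genes of mitosis, 37 rose, none fell and 19 did not pass; adjusted over the list alone, 53 rose. Anln rose by a log2 fold change of 3.32 (SE 0.34), Spc24, a kinetochore subunit, by 2.98 (SE 0.38), the spindle motor gene Kif11 by 2.41 (SE 0.35) and the checkpoint kinase gene Bub1b by 3.12 (SE 0.44). The mean log2 fold change of the list was 3.19 (camera adjusted p = 2.31e-48; adjusted p = 0.311 with an estimated correlation). The mean log2 CPM of the list was 0.03, 3.21, 1.85 and 1.70 in GSK8573 libraries 1 to 4 and between 5.19 and 5.58 in the GSK2801 libraries, a difference of 3.68 (95% interval 1.98 to 5.55; exact permutation p = 0.02857, adjusted p = 0.110). The mean was 2.71 without GSK8573 libraries 1 and 4, where 36 of 59 genes rose and none fell. Leaving out GSK8573 library 3 or 4 gave 17 or 23 genes that rose, and leaving out GSK2801 library 1, 2, 3 or 4 gave 13, 12, 14 or 15.

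Of 41 tested genes of DNA replication, 2 rose, none fell and 39 did not pass; adjusted over the list alone, 12 rose. The 2 were Tk1, which encodes thymidine kinase (log2 fold change 2.63, SE 0.41), and Fen1, a flap endonuclease (1.90, SE 0.47). The mean was 1.15 (camera adjusted p = 2.06e-10; adjusted p = 0.392 with an estimated correlation), and the score difference was 1.39 (0.38 to 2.93; exact permutation p = 0.02857, adjusted p = 0.110). The DNA replication score was 1.36, 3.17, 3.27 and 2.50 in GSK8573 libraries 1 to 4, and without libraries 1 and 4 the mean was 0.62 and 7 of 44 genes rose. Leaving out GSK8573 library 1 or 3 gave 8 or 4 replication genes that rose, and without GSK2801 library 1, 2 or 4 the count was 1. With library totals alone 9 rose. The 42 replication-dependent histone genes were listed as a sign of RNA quality, since their transcripts mostly lack a poly(A) tail. Like them, reads not assigned to a gene were higher with GSK2801 (67.6% with GSK8573 and 70.8% with GSK2801). Within GSK2801 the 2 did not go together, since library 3 had the most unassigned reads (72.6%) and the lowest histone share of counts (0.0630%). The histone score was -0.096, 2.36, 1.55 and 1.04 in GSK8573 libraries 1 to 4, which ranks them as the mitosis score does. Of the histone genes, 5 rose, among them H1f3 (log2 fold change 1.39, SE 0.28), H2bc3 (3.32, SE 0.80), H3c2 (4.15, SE 1.04) and H2bc14 (4.39, SE 1.13), with H2ac20 (1.33, SE 0.35) named after its value was seen. None fell, 37 did not pass and 13 rose when adjusted over the list alone; the mean was 1.71 (camera adjusted p = 2.56e-13; adjusted p = 0.338 with an estimated correlation). Histone genes are near-identical copies, so single members are uncertain. Without GSK8573 library 3 the GSK8573 means of H2bc3 and H3c2 go from 0.922 to 0.605 and from 0.220 to 0.126 CPM, and without GSK8573 library 2 that of H2bc14 goes from 0.126 to 0.0413. These 3 missed the threshold in 4, 7 and 12 of 22 alternatives. The histone count was 8 of 46 without GSK8573 libraries 1 and 4, and 9 or 10 without GSK8573 library 1 or 2. It was 0, 1, 1 or 1 without GSK2801 library 1, 2, 3 or 4, and 12 with library totals alone.

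**Figure D2:**
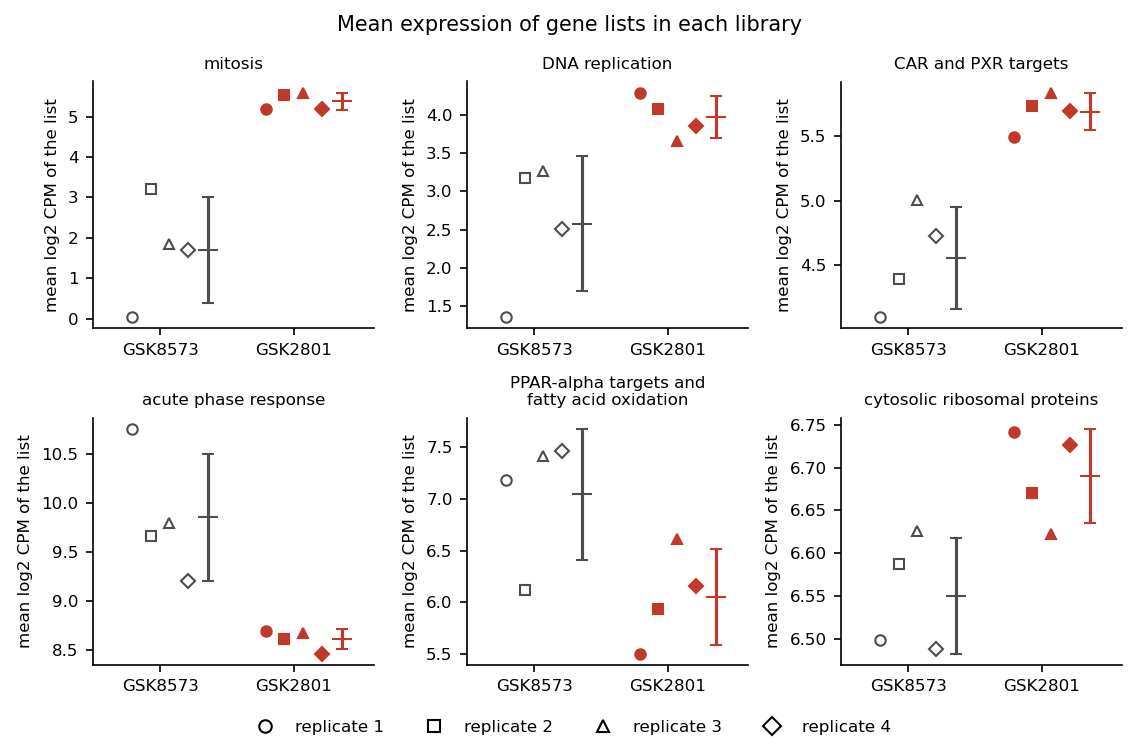
Each point is 1 library, with the mean log2 CPM of a gene list on the vertical axis for 6 lists, and bars give the group mean and SD (n = 4). The mitosis score lay between 0.03 and 3.21 in the GSK8573 libraries and between 5.19 and 5.58 in the GSK2801 libraries.

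Of 36 tested acute phase genes, 20 fell, none rose and 16 did not pass; adjusted over the list alone, 27 fell. They included Lrg1 (log2 fold change -1.47, SE 0.18), Hp (-1.69, SE 0.24), Cp, which encodes ceruloplasmin (-1.601, SE 0.24), and Itih3 (-1.23, SE 0.22). The list mean was -1.44 (camera adjusted p = 8.98e-24; adjusted p = 0.311 with an estimated correlation), and the score difference was -1.24 (-2.28 to -0.50; exact permutation p = 0.02857, adjusted p = 0.110). The complement gene C3, named after its values were seen, made up 6.23% of the counts of GSK8573 library 1, 4.386% to 4.601% of the other GSK8573 libraries and 2.71% to 3.03% of the GSK2801 libraries. The mean was -1.11 and 19 genes fell without GSK8573 libraries 1 and 4, and without GSK2801 library 1, 2 or 4 the count was 11, 7 or 11. Of 54 other secreted plasma proteins, 7 fell, among them Apoa5, Kng1 (log2 fold change -1.23, SE 0.17), Hrg (-0.91, SE 0.14) and C4bp (-0.87, SE 0.15), and 44 did not pass. The 3 that rose were Ttr, F13b and Serpinf1 (0.74, 0.70 and 0.88), named after their values were seen. Adjusted over the list alone, 3 rose and 17 fell; the mean was -0.22, which turned to 0.12 with library totals alone (camera adjusted p = 0.00119; adjusted p = 0.475 with an estimated correlation). Of the secreted protein genes, 12 fell without GSK8573 libraries 1 and 4, and 11 without GSK8573 library 1 alone. The number that rose was 1, 0 or 1 without GSK2801 library 1, 2 or 3, and 2 without GSK8573 library 3 or GSK2801 library 4. With GC and length offsets 1 rose and 15 fell, and with library totals alone 4 rose and 3 fell.

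Of 40 tested targets of the nuclear receptors CAR and PXR, 10 rose, 3 fell and 27 did not pass; adjusted over the list alone, 13 rose and 4 fell. Cyp3a11, a cytochrome P450 of drug metabolism, had 1012 ± 300 CPM with GSK8573 and 5618 ± 1003 with GSK2801 (log2 fold change 2.47, SE 0.24). The transporter gene Slco1a4 rose by 1.80 (SE 0.32) and the aldo-keto reductase gene Akr1b7 by 4.74 (SE 0.86). Without GSK2801 library 4 the GSK2801 mean of Akr1b7 goes from 8.18 to 4.984 CPM and the gene did not pass (log2 fold change 4.05, adjusted p = 0.0538); without GSK8573 library 4 its log2 fold change was 5.496, and it missed the threshold in 2 of 22 alternatives. Alas1, the first enzyme of haem synthesis, fell (-1.603, SE 0.27). The acute phase genes Orm1 (-1.74) and Orm2 (-1.42) fell as well and were named after their values were seen. The list mean was 0.997 (camera adjusted p = 0.000176; adjusted p = 0.311 with an estimated correlation), and the score difference was 1.13 (0.49 to 1.74; exact permutation p = 0.02857, adjusted p = 0.110). Of these targets, 9 rose and 1 fell without GSK8573 libraries 1 and 4. Without GSK8573 library 3 or GSK2801 library 2 or 4, 6, 6 or 4 rose, and 1 fell without GSK2801 library 2 or 4.

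Of 29 tested NRF2 targets, 6 rose, 1 fell and 22 did not pass; adjusted over the list alone, 8 rose and 1 fell. Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, had 173.6 ± 22.8 CPM with GSK8573 and 474.6 ± 65.9 with GSK2801 (log2 fold change 1.45, SE 0.15). The glutathione transferase genes Gsta1 (5.11, SE 1.05), Gstm1 (1.69, SE 0.33) and Gstm3 (4.40, SE 0.75) rose as well and are also on the list of CAR and PXR targets. The 7 GSK8573 counts of Gsta1 lay in library 2, and without it the group is at 0, so its fold rests on that library, and it missed the threshold in 2 of 22 alternatives (adjusted p up to 0.0591). Hmox1, which encodes haem oxygenase, fell (-0.997, SE 0.28; adjusted p = 0.0496) and was named after its value was seen. The mean was 0.80 (camera adjusted p = 0.000703; adjusted p = 0.412 with an estimated correlation). Without GSK8573 libraries 1 and 4, 7 NRF2 targets rose and none fell, and with library totals alone 9 rose and none fell. The number that rose was 3, 2, 4 or 3 without GSK8573 library 3 or GSK2801 library 1, 2 or 4. Hmox1 did not pass with RLE scaling, nor without GSK8573 library 1 or 3 or GSK2801 library 1, 2 or 3. Members of the Cyp3a, Cyp2a, Gsta and Gstm families share long stretches of sequence, so single members are uncertain.

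Of 31 interferon-stimulated genes, Oasl1 (log2 fold change 2.82, SE 0.47) and Bst2 (1.07, SE 0.26) rose, none fell and 29 did not pass; adjusted over the list alone, 19 rose. The mean was 1.32 (camera adjusted p = 5.92e-09; adjusted p = 0.311 with an estimated correlation). The interferon score was 1.57, 2.25, 1.80 and 1.54 in GSK8573 libraries 1 to 4 and 2.89 to 3.52 in the GSK2801 libraries, and 3 of 33 genes rose without GSK8573 libraries 1 and 4. The number of interferon-stimulated genes that rose was 4 without GSK8573 library 2 or 4, and 1 without GSK8573 library 3 or any of the GSK2801 libraries; with library totals alone it was 16. Of 17 cytokine and chemokine genes, Ccl9 (3.002, SE 0.31) and Cxcl9 (2.51, SE 0.59) rose and 15 did not pass, with 2 adjusted over the list alone. The cytokine mean was -0.27, against 0.12 with library totals alone (adjusted p = 0.738, camera). The count was 1 without GSK8573 library 3 or 4 or GSK2801 library 1 or 2.

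Of 39 tested PPAR-alpha targets and genes of fatty acid oxidation, 12 fell, none rose and 27 did not pass; adjusted over the list alone, 26 fell. Hadha and Hadhb, the subunits of the mitochondrial trifunctional protein, fell with log2 fold changes of -1.12 (SE 0.18) and -1.04 (SE 0.22). Etfdh (-1.08, SE 0.20) and the carnitine carrier gene Slc25a20 (-0.90, SE 0.19) fell as well. The mean was -1.05 (camera adjusted p = 4.62e-14; adjusted p = 0.392 with an estimated correlation), and the score difference was -0.99 with an interval that includes 0 (-1.96 to 0.50; exact permutation p = 0.0857). Of these genes 5 fell without GSK8573 libraries 1 and 4, and 3 with library totals alone. The number of fatty acid oxidation genes that fell was 20 without GSK8573 library 2, 6 without GSK8573 library 3, and 3, 2 or 4 without GSK2801 library 1, 2 or 4. Among 18 genes of gluconeogenesis and glycogen, Pck1 (-1.24, SE 0.18) and Fbp1 (-0.95, SE 0.19), enzymes of glucose synthesis, fell, and Gbe1 (0.69, SE 0.16) and Pygl (0.98, SE 0.23), enzymes of glycogen, rose. The other 14 did not pass, and adjusted over the list alone 3 rose and 3 fell. The gluconeogenesis list had a mean of -0.32, against 0.01 with library totals alone, and was not called (adjusted p = 0.200), but it was called without GSK8573 library 1 (adjusted p = 0.0391). No member rose without GSK8573 library 3 or GSK2801 library 1, 2 or 4, 1 rose without GSK2801 library 3, and 1 fell without GSK2801 library 1 or 2. With GC and length offsets 0 rose and 3 fell. Among 41 genes of the urea cycle and amino acid catabolism, 4 rose, including Kmo (0.97, SE 0.16), Hal (1.07, SE 0.19) and the X-linked urea cycle gene Otc (3.51, SE 0.63), 3 fell, including Mat1a, and 34 did not pass. Gpt2 (-0.99) was another that fell, and Ass1 (0.85), which rose, and Arg1 (-0.79), which fell, were named after their values were seen. Adjusted over the list alone, 4 rose and 4 fell, and the list's mean of 0.01, its median of -0.03 and its test differed in sign. The urea cycle list was not called (adjusted p = 0.977), and its mean was -0.03 with upper-quartile scaling. The number that rose was 2 without GSK8573 library 3 or GSK2801 library 1, 2 or 4; 5 fell without GSK8573 library 1, and 1 without GSK2801 library 1, 2 or 4.

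Of 72 tested cytosolic ribosomal protein genes, 20 rose, 6 fell and 46 did not pass; adjusted over the list alone, 33 rose and 25 fell. Rps15a rose by a log2 fold change of 0.92 (SE 0.14), Rpl32 by 0.71 (SE 0.11) and Rpl7a by 0.78 (SE 0.13). The mean of the ribosomal list was 0.13 and it was not called (adjusted p = 0.200); the score difference was 0.14 (95% interval -0.004 to 0.25; exact permutation p = 0.0571). The direction of the list mean depends on the scaling. With GC and length offsets 10 rose, 27 fell and the list mean was -0.11, against a median of -0.14 for all genes. With library totals alone 33 rose, none fell and the list mean was 0.47, against a median of 0.34 for all genes. Of the ribosomal genes, 14 rose and 6 fell without GSK8573 libraries 1 and 4, and 9 or 1 fell without GSK8573 library 1 or 3. Without GSK2801 library 1, 2, 3 or 4, 9, 10, 13 or 11 rose and 0, 0, 0 or 2 fell. Ribosomal protein genes have many pseudogenes and near copies, so single members are uncertain.

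Among 62 ribosome biogenesis genes, Nat10, an RNA acetyltransferase, rose (log2 fold change 0.59, SE 0.16), none fell and 61 did not pass, with 0 adjusted over the list alone. Nat10 did not pass when any of the 8 libraries was left out, and 2 other members fell without GSK8573 library 2. Without GSK2801 library 4 the list was called lower (adjusted p = 0.04966). The biogenesis list had a mean of -0.11 (adjusted p = 0.110) and a score difference of -0.10 (-0.34 to 0.13; exact permutation p = 0.200), which turned to 0.24 with library totals alone. None of 19 RNA polymerase I genes changed by edgeR, DESeq2 or limma-voom, while 2 had an unadjusted p under 0.05, Cd3eap (-0.70, SE 0.25) and Polr2e (-0.58, SE 0.22); none passed adjusted over the list alone. The polymerase I score difference was -0.14 (-0.53 to 0.17; exact permutation p = 0.286), and the list mean of -0.17 turned to 0.17 with library totals alone. Of 38 translation factor genes, Eif1a (-0.77, SE 0.15) and Eef2 (-0.67, SE 0.14) fell and 36 did not pass, with 2 adjusted over the list alone. The translation factor score difference was -0.12 (-0.29 to 0.07; exact permutation p = 0.114), against 0.22 with library totals alone. The list, not called here (adjusted p = 0.0631), was called with GC and length offsets (adjusted p = 0.01004) and without GSK2801 library 4 (adjusted p = 0.0419). Of its members 4 fell without GSK8573 library 1, and 1 without GSK2801 library 1 or 2. Of 14 aminoacyl-tRNA synthetase genes, Vars (1.21, SE 0.19), Rars (0.82, SE 0.19), Iars (0.72, SE 0.17) and Aars (0.52, SE 0.13) rose, none fell and 10 did not pass, with 6 that rose adjusted over the list alone. The synthetase mean was 0.33 (camera adjusted p = 0.0249; adjusted p = 0.311 with an estimated correlation). The synthetase call ended with GC and length offsets (adjusted p = 0.0663, 2 rose), where the mean went from 0.33 (SD over members 0.42) to 0.18 (SD 0.44), and without GSK8573 library 2 (adjusted p = 0.0757, 2 rose) or 3 (adjusted p = 0.0624, 1 rose). Without GSK2801 library 1, 2, 3 or 4, 1, 2, 2 or 1 rose, and 4 rose without GSK8573 libraries 1 and 4.

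Of 30 growth factors and receptors of liver regeneration, 6 fell, including Egfr, the receptor of epidermal growth factor (log2 fold change -1.04, SE 0.19), Il6st, the shared receptor of interleukin-6 family cytokines (-0.74, SE 0.12), and Inhbe, an activin subunit (-2.02, SE 0.34). Erbb3 rose (0.93, SE 0.18) and 23 did not pass; adjusted over the list alone, 1 rose and 8 fell. The regeneration list mean was -0.32, which turned to 0.02 with library totals alone (camera adjusted p = 0.0367; adjusted p = 0.311 with an estimated correlation), and 1 rose and 6 fell without GSK8573 libraries 1 and 4. With GC and length offsets, which put the median of all genes at -0.14, the regeneration mean moved further from 0, to -0.45 (SD over members 0.96, before and after), and 6 still fell, but the list was no longer called against the other genes (adjusted p = 0.0663). The call also ended with genes of 1 transcript (adjusted p = 0.0532) and without GSK8573 library 2 (adjusted p = 0.0574); 4 or 3 fell without GSK8573 library 3 or GSK2801 library 1. Without GSK2801 library 2, 3 or 4, 4, 4 or 3 of them fell, and without GSK8573 library 4, 2 rose and 8 fell. Of 28 unfolded protein response genes, Dnajb9, a chaperone gene, fell (-1.07, SE 0.21) and 27 did not pass, also adjusted over the list alone. The unfolded protein list mean was -0.24, which turned to 0.12 with library totals alone (camera adjusted p = 0.0396; adjusted p = 0.702 with an estimated correlation). The unfolded protein call ended with library totals alone (camera adjusted p = 0.280) and with the replicate block (adjusted p = 0.0641, mean -0.22). It also ended without GSK8573 libraries 1 and 4 (adjusted p = 0.198) and without GSK8573 library 1 (0.344) or 2 (0.0538). Without GSK2801 library 3 (0.0845) or 4 (0.0576), as adjusted p-values, it ended as well. Of these genes 2 fell without GSK8573 library 4.

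Markers of other liver cells were measured in the same libraries. Of 27 endothelial markers, Flt1 (log2 fold change -0.92, SE 0.22) and Gpr182 (-0.92, SE 0.22) fell and 25 did not pass, with 3 that fell adjusted over the list alone. The endothelial mean was -0.36 (camera adjusted p = 0.0319; adjusted p = 0.359 with an estimated correlation) and the score difference was -0.28 (-0.61 to 0.03; exact permutation p = 0.0857). The endothelial call ended without GSK8573 library 3 (adjusted p = 0.0624, 1 fell), GSK8573 library 4 (0.0659, 1 fell) or GSK2801 library 3 (0.0845, none fell). With GC and length offsets it ended as well (adjusted p = 0.0663), while the mean moved from -0.36 to -0.46 (SD over members 0.50, before and after) and 3 fell; with library totals alone the mean was -0.02 and none fell. None fell without GSK2801 library 1 or 2, 1 fell without GSK2801 library 4 and 1 without GSK8573 libraries 1 and 4. None of 21 Kupffer cell and macrophage markers changed by edgeR or limma-voom, 3 had an unadjusted p under 0.05 and DESeq2 called 1; C1qa had a log2 fold change of -0.59 (SE 0.21). With library totals alone 1 marker rose, and with GC and length offsets 1 fell. The Kupffer cell score difference was 0.18 (-0.48 to 1.05; exact permutation p = 0.571), and the list mean of 0.01 was -0.03 with upper-quartile scaling. Of 25 stellate cell and fibroblast markers, Hhip (-1.75, SE 0.39) and Hgf (-1.07, SE 0.25) fell and 23 did not pass, also adjusted over the list alone. The stellate score difference was 0.37 (-0.27 to 0.97; exact permutation p = 0.200). None fell without GSK8573 library 3 or GSK2801 library 3 or 4, 1 fell without GSK2801 library 1 or 2, and 1 rose without GSK8573 library 1 or 4. Without GSK8573 libraries 1 and 4 together, 2 rose and 1 fell.

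**Figure D3:**
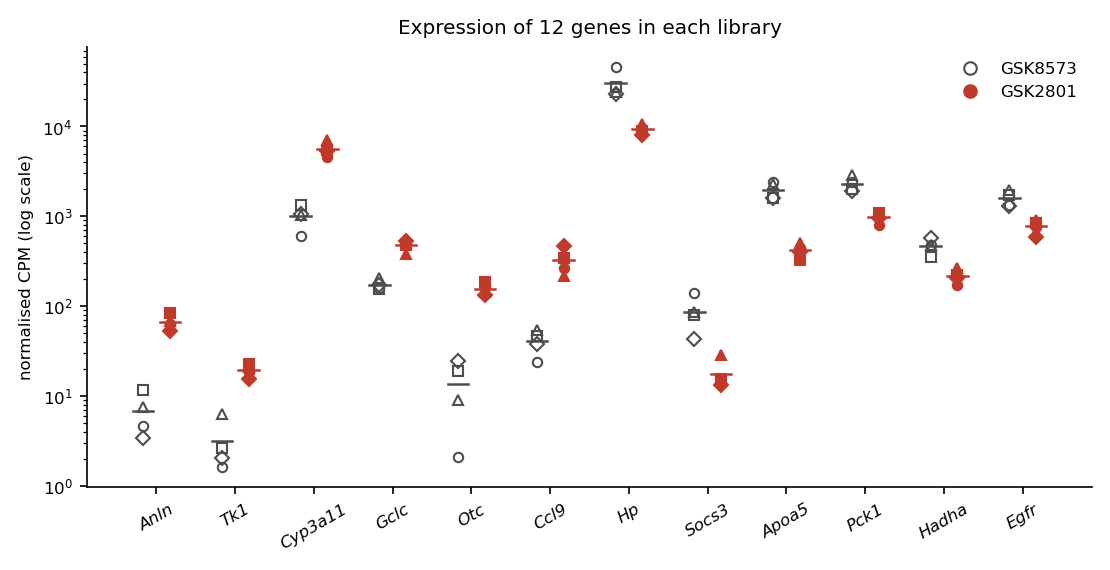
CPM of 12 genes in each library on a logarithmic vertical axis, with points for libraries and bars for group means (n = 4). Anln lay at 6.79 ± 3.65 CPM (SD) with GSK8573 and 67.1 ± 13.02 with GSK2801, and Apoa5 at 1975 ± 428 and 419 ± 74.7.

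The libraries also differed in composition. The 20 most abundant genes held 37.9 ± 4.96% of counts with GSK8573, with 45.3% in library 1 and 34.8% to 36.5% in the other 3, and 29.0 ± 0.578% with GSK2801. With GSK8573 they include acute phase genes such as Hp (2.2% to 3.427% of counts, against 0.921% to 1.166% with GSK2801). This measure is therefore not separate from the fall of acute phase genes. Genes detected with 1 count or more numbered 12640 ± 452 with GSK8573 and 13480 ± 279 with GSK2801. Replication-dependent histones held 0.0320 ± 0.00877% and 0.0714 ± 0.00763% of counts, haemoglobin genes 0.000331 ± 0.000176% and 0.00152 ± 0.000739%, and reads not assigned to a gene made up 67.6 ± 0.798% and 70.8 ± 1.44%. Each of these 5 measures separated the groups at the smallest exact permutation p that 4 against 4 libraries allow (0.02857), with an adjusted p of 0.0343 over the 6 measures fixed beforehand. Over all 11 measures computed the adjusted p was 0.0524, which misses the threshold, and the division into 6 and 5 was made after that result was seen. Total counts, the other of the 6, did not separate the groups (exact permutation p = 0.171). Correlations of log2 CPM were 0.932 to 0.946 within GSK2801, 0.869 to 0.926 within GSK8573 and 0.828 to 0.917 between the groups, and the first principal component held 39.1% of the variance.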

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

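The tests of the mitosis and acute phase patterns and of the spread of ribosomal protein values were chosen only after those results were seen; the divisions of the libraries, the calls of ribosomal genes with GC and length offsets and the search for shared sequence were set out before.

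A library lay far from the other 3 of its group, by Dixon's criterion at the 95% level, in 29 of 379 groups of values tested (7.65%), where chance flags about 1 in 20. GSK8573 libraries 1 to 4 accounted for 7, 4, 0 and 3 of these, and GSK2801 libraries 1 to 4 for 3, 2, 4 and 6.

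The 20 most abundant genes held 45.29% of counts in GSK8573 library 1, above the rest of its group, and 28.13% in GSK2801 library 2, below the rest. Reads aligned more than once made up 27.82% in GSK2801 library 4, below the rest of its group. In GSK8573 library 1 the mean log2 CPM was low for pericentral hepatocyte genes (4.662) and for mesothelial markers (0.4532), and in GSK8573 library 4 it was low for immediate early genes (3.217). Among GSK2801 libraries, the score was low for RNA polymerase I genes in library 1 (3.086), high for ATF4 targets in library 3 (3.759), and low in library 4 for secreted plasma proteins (9.33) and male-biased genes (5.277).

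Among single genes in GSK8573, library 1 had the highest CPM of Ska3 (0.6195), Gipc2 (0.1239), Csad (261.4) and Dnajb9 (343.6), and library 2 that of Arhgef39 (0.2528), Serpinb8 (0.8848), Gbe1 (100.1) and Gsta1 (0.8848). Amotl1 was high (45.62) and Kng1 low (129.4) in GSK8573 library 4. In GSK2801, Clec2h (9.748) and Fen1 (33.12) were high in library 1 and Psma1 (81.82) in library 2. Socs3 (28.58), Mrps22 (26) and Fn1 (7253) were high in GSK2801 library 3, and in library 4 Ces1a was high (6.38) and Ska3 (9.935) and Csad (8.203) were low.

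The number of genes that changed was 710, and 1 of the 35 divisions of the 8 libraries into 4 and 4, the real one, gave as many. The highest other gave 1, which argues against chance for the gene count. It cannot exclude chance, since there are only 35 divisions and each of the others mixes the groups. Nor can it separate the compound from another difference that follows the groups. For the 13 list calls by camera, 16 of the 35 divisions gave as many and the highest other gave 19, so chance cannot be excluded for the number of lists called.

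The first pattern is that mitosis genes were higher with GSK2801. On a few genes taking most of the counts, the list mean was 3.1457 or more with RLE, upper-quartile and library-total scaling and without the 20 most abundant genes. Scaling moves all genes by a similar amount, and their median moved to 0.34 with library totals alone, so this test could hardly have come out otherwise. It shows only that such a shift is small beside the main list mean of 3.19. GSK8573 libraries 1 and 4 are argued against as the whole source, since the mean without them was 2.7132. A lower share of hepatocytes was assumed to raise the markers of other cell types alike. It was tested on Kupffer cell, endothelial and stellate markers, 3 lists chosen in place of an earlier version after the values had been seen. Their highest upper bound of the score difference was 1.053, below the lower bound of 1.978 for mitosis. This argues against such an even rise as the source, and not against a rise of a single other cell type. The bounds of 2 smaller lists of 7 genes reach that level, erythroid cells (1.08, 0.09 to 2.58) and mesothelium (0.39, -0.66 to 2.17), and more mesothelial cells stay open. Neutrophils, T and NK cells and B and plasma cells had too few measured genes to test. For dividing erythroid cells, the summed CPM of the haemoglobin genes was 19.87 at most in a GSK2801 library while that of the mitosis genes rose by 2916 or more. An unknown part of the haemoglobin reads may be lost between near-identical copies, so this sets no firm bound. The erythroid membrane gene Slc4a1 was at 1.823 CPM at most with GSK2801 and 1.871 with GSK8573. This argues against dividing erythroid cells as the source, though it rests on 1 gene with few counts. A candidate explanation that also stays open and untested is the compound itself, and the labels name no batch that could be tested against it.

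The second pattern is that acute phase genes were lower with GSK2801. The list mean was -1.0468 or lower in the same 4 settings. This cannot decide on a few genes taking most of the counts, since acute phase genes such as C3 and Hp are themselves among the most abundant. GSK8573 libraries 1 and 4 are argued against as the whole source, since the list mean was -1.1085 without them. The compound, or a difference in the inflammation that follows surgery, may contribute and was not tested.

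The third pattern is that ribosomal protein genes moved apart, 20 up and 6 down. The spread of their log2 fold changes was 0.5549 (SD) with GC and length offsets against 0.5423 without. This argues against a trend on GC content and length shared by all genes as the cause of the spread. An effect of GC content or length particular to these genes was not tested. Of the 26 called genes 16 were called in the same direction with the offsets, 10 of the 20 that rose and 6 of the 6 that fell, so for the direction of single genes this explanation stays open. Reads shared with pseudogenes or paralogs cannot be told apart from a change of the genes themselves, since 71 of 72 genes share 1% or more of their 50-base stretches with another annotated gene and 0% of the 1 other gene was called; against it, the share did not go with the log2 fold change (Spearman rho -0.062) or its size (rho 0.030) across the 72 genes.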

How the results depend on the processing

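Library totals alone, GSK8573 libraries 1 and 4 left out, genes with 1 transcript and transcripts as deposited were tried only after the data were seen. Of the 131 genes that the rule names, 112 passed the test and 0 of these turned direction in the 22 alternatives, while of the 19 others 2 turned, Baz2a (-0.041 to 0.36) and Cd3e (-1.04 to 0.28), which passed in none. RLE scaling and a mean CPM of 1 or more left each of them on its side of the threshold; the numbers no longer past it were highest without GSK2801 library 1 (53) and 2 (47). The same-numbered libraries of the 2 groups did not go together (correlations of deviations -0.017, 0.053, -0.015 and -0.051), so the numbers were not used to pair; with the replicate block 189 genes fell, and list scores were not run under it. GC and length offsets gave 604 lower genes and called nuclear oxidative phosphorylation genes lower (mean -0.35, adjusted p = 1.63e-05). They also called translation factors (mean -0.29, adjusted p = 0.01004, and mean -0.28 together with the block). Score differences with the offsets were -0.34 for ribosomal proteins, which turned from 0.14, and -0.38 for ribosome biogenesis, from -0.10. They were -0.43 for RNA polymerase I, from -0.14, and -0.44 for translation factors, from -0.12. Each was at the smallest permutation p (0.02857). The means of these lists moved less, from 0.13, -0.11, -0.17 and -0.13 to -0.11, -0.26, -0.32 and -0.29, in the same order. The scores may therefore overstate the effect of the offsets, and no conclusion is drawn from their sizes or permutation p. The block with the offsets gave 249 higher genes. The cause of these shifts was not tested. TREAT against 1.2-fold, a stricter test by construction, gave 265 higher and 142 lower genes, and DESeq2 gave 696 and 468.

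With library totals alone, 1099 genes were higher and 92 lower; the means of the lists of the unfolded protein response (0.12), regeneration factors (0.022) and secreted plasma proteins (0.12) turned positive, as did the scores of ribosome biogenesis (0.24) and translation factors (0.22), and ribosomal proteins were called (mean 0.47, score 0.49). This setting shifts all genes up by construction. With an estimated inter-gene correlation 0 lists were higher and 0 lower, with adjusted p-values of 0.311 for mitosis (mean 3.19) and 0.392 for DNA replication (1.15). Fry also called RNA polymerase I (mean -0.17), translation factors (-0.13), G1 cyclins and periportal genes. It did not call DNA replication (adjusted p = 0.0507), endothelial cells (0.0507), PPAR-alpha targets and fatty acid oxidation (0.0568), secreted plasma proteins (0.0568) or the unfolded protein response (0.297). No count filter gave 11 higher lists and called ribosome biogenesis (-0.12). Upper-quartile scaling called translation factors (-0.17), as did genes with 1 transcript (-0.16), with scores of 0.12 for ribosomal proteins and -0.15 for translation factors at an unadjusted permutation p under 0.05. These permutation p-values were not adjusted over lists, which in the main test took the smallest possible p of 0.02857 to 0.110. Without GSK8573 libraries 1 and 4, the scores were 0.048 for ribosomal proteins, -0.017 for translation factors, whose list mean turned to 0.14, and 0.64 for DNA replication. Genes were filtered anew there, with 11426 tested against 10622, so these values may cover other list members.

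Leaving out each library in turn, which also lowers the number of samples, gave 177 (without GSK2801 2) to 507 (without GSK8573 2) higher genes, 84 (without GSK2801 2) to 318 (without GSK8573 2) lower genes and 6 (without GSK8573 2) to 11 (without GSK8573 4) higher lists. The mean for ribosome biogenesis ranged from -0.156 (without GSK8573 2) to -0.088 (without GSK2801 1) and that for translation factors from -0.14 (without GSK2801 4) to 0.052 (without GSK2801 2), whose score ranged from -0.13 (without GSK8573 4) to 0.0071 (without GSK2801 2). Without GSK2801 2, genes were filtered anew and 10942 were tested against 10622, so the 0.052 and 0.0071 may cover other members. Over the 38 members of the main test, translation factor scores were 6.046, 5.942 and 6.138 in GSK2801 libraries 1, 3 and 4. They were 6.072 to 6.212 with GSK8573. Where not stated, causes were not tested. In simulated data with the same spread in both groups, unlike these libraries, 31% of 2-fold and 67% of 4-fold changes were called.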

Other observations

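In this part, counts without GSK8573 libraries 1 and 4 together, with library totals alone and with genes of 1 transcript come from settings chosen only after the data were seen. Genes that mark the sex and zonation of hepatocytes were measured as well, with 50 lists adjusted together by camera. Of 26 male-biased genes, the urinary protein gene Mup17 (log2 fold change 2.56, SE 0.38) and the steroid enzyme gene Hsd3b5 (5.73, SE 1.11) rose, Egfr fell and 23 did not pass; adjusted over the list alone, 2 rose and 1 fell. Hsd3b5 missed the threshold in 6 of 22 alternatives (adjusted p up to 0.512), and without GSK8573 library 2 its GSK8573 mean goes from 0.473 to 0.125 CPM. The male-biased mean was 0.68 (adjusted p = 0.0524), called without GSK8573 library 1 (adjusted p = 0.0256) or GSK2801 library 4 (adjusted p = 0.00161), with the replicate block (0.0239), upper-quartile scaling (0.0440), no count filter (0.0198) and genes of 1 transcript (0.0159), as adjusted p-values. Without GSK8573 library 1, 4 male-biased genes rose, and 1 rose without GSK8573 library 3 or GSK2801 library 1 or 2. Of 17 female-biased genes, Nipal1 (3.02, SE 0.44) rose and 16 did not pass, also over the list alone; the mean was 0.31, and the list was called without GSK8573 library 4 (mean 1.14, adjusted p = 0.00513), when 2 rose, and without GSK8573 libraries 1 and 4 (mean 1.06, adjusted p = 0.0103). The female-biased mean was 0.52 or 0.69 without GSK8573 library 2 or 3, and 0.65 or 0.20 without GSK2801 library 1 or 4. Of 30 periportal genes, 5 rose, including Hal and Aldh1b1 (1.30, SE 0.28), 3 fell, including Pck1 and Fbp1, and 22 did not pass; Cdh1 (1.53), Ass1 (0.85), Hsd17b13 (1.64) and Arg1 (-0.79) were named after their values were seen. Adjusted over the list alone, 5 periportal genes rose and 4 fell; 2, 1, 3 or 3 rose without GSK8573 library 3 or GSK2801 library 1, 2 or 4, and 1, 1 or 2 fell without GSK2801 library 1, 2 or 4. Of 35 pericentral genes, Gstm3 and Cyp2a5 (4.76, SE 0.97) rose, Slc13a3 (-1.32, SE 0.24) fell and 32 did not pass; over the list alone 2 rose and 1 fell. Cyp2a5 missed the threshold in 11 of 22 alternatives, among them without GSK2801 library 3 (log2 fold change 4.03, adjusted p = 0.0525), where its GSK2801 mean goes from 163.9 to 98.38 CPM. Without GSK8573 library 3 no pericentral gene rose, 3 fell without GSK8573 library 1 or 4, 1 rose without GSK8573 library 1 or GSK2801 library 2, 3 or 4, and 1 rose and 5 fell without GSK8573 libraries 1 and 4. Of 23 genes of bile acid synthesis and transport, Slco1a4 and Slc27a5 (0.58, SE 0.15) rose and 21 did not pass, also over the list alone; the list was called without GSK8573 library 4 (adjusted p = 0.0479) or GSK2801 library 4 (adjusted p = 0.0419), with no count filter (0.0297) and with genes of 1 transcript (0.0436), and 1 member rose without GSK8573 library 3 or GSK2801 library 1 or 2.

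Among 21 G1 cyclins and cell cycle inhibitors, the inhibitor genes Cdkn2d (3.17, SE 0.66), Cdkn2c (1.55, SE 0.32) and Cdkn1b (0.83, SE 0.19) rose and 18 did not pass; over the list alone 6 rose and 1 fell, and 1 or 0 rose without GSK2801 library 1 or 2. Among 23 immediate early genes, Junb (-1.37, SE 0.31) and Klf10 (-2.12, SE 0.53) fell, Klf6 (0.91, SE 0.23) rose and 20 did not pass; the mean was -0.42 (adjusted p = 0.0941), and the list was called lower without GSK8573 library 4 (adjusted p = 0.00738), GSK2801 library 4 (0.0444) or GSK8573 libraries 1 and 4 (0.0276) and with library totals alone (0.0281, mean -0.06). Klf10 missed the threshold in 12 of 22 alternatives, and without GSK2801 library 3 its log2 fold change was -2.73. No immediate early gene fell without GSK2801 library 2 or 4, 1 fell without GSK8573 library 3 or GSK2801 library 1, and Klf6 did not pass without GSK8573 library 3 or 4 or GSK2801 library 2, 3 or 4. Several lists had 1 or 2 called genes: Fas (-1.17) of 22 p53 targets, Ebp (0.81) of 23 cholesterol genes, Acss2 (1.34) and Elovl5 (-0.69) of 23 lipid synthesis genes and Gpt2 (-0.99) of 23 ATF4 targets. Others were Hspb8 (-0.96) of 17 heat shock genes, Bhlhe40 (-0.70) of 19 clock genes, Mrps22 (0.83) and Mrpl17 (-0.78) of 73 mitochondrial ribosomal genes, Fn1 (-1.19) of 38 matrix genes and Gsta1 of 10 aryl hydrocarbon receptor targets. With adjustment over each list alone, 3 ATF4 targets rose and 4 fell, and 2 p53 targets rose and 1 fell. In the same way 2 cholesterol genes rose and 0 mitochondrial ribosomal genes passed. Of 73 nuclear oxidative phosphorylation genes, Sdhb (0.53) rose and 72 did not pass, with 0 adjusted over the list alone; 18 of the 73 values were positive and the mean was -0.09 (adjusted p = 0.0858). With GC and length offsets 0 rose and 11 fell and the list was called lower (mean -0.35, adjusted p = 1.63e-05), as it was without GSK8573 library 1 (0.0215), without GSK8573 libraries 1 and 4 (0.0352) and with no count filter (0.0402), as adjusted p-values. With library totals alone the mean was 0.24 and 4 rose. Among cell markers single calls were Onecut1 (-1.36) of 14 for cholangiocytes, Dpp4 (1.04) of 7 for mesothelium, Tfrc (0.81) of 7 for erythroid cells (score difference 1.08, 95% interval 0.09 to 2.58, exact permutation p = 0.02857, adjusted p = 0.110) and Tff3 (4.41, or 4.93 without GSK8573 library 3) of 5 for gallbladder and intestine. These counts moved with single libraries. Without GSK2801 library 1, members passed only for cholesterol, erythroid cells and gallbladder (1 each). Without GSK2801 library 2 they passed for these 3, for aryl hydrocarbon receptor targets and for mitochondrial ribosomal genes (1 each). Without GSK2801 library 3, 0 passed for clock, oxidative phosphorylation, mitochondrial ribosomal, cholangiocyte and mesothelial genes, 2 ATF4 targets fell, 2 cholesterol genes rose and 0 lipid synthesis genes fell. Without GSK2801 library 4 members passed only for p53 targets, matrix and gallbladder (1 each) and cholesterol (2). Without GSK8573 library 3 they passed only for cholesterol, matrix, aryl hydrocarbon receptor targets, cholangiocytes, erythroid cells and gallbladder (1 each). Leaving out GSK8573 library 1 gave 2 rising genes each for lipid synthesis, aryl hydrocarbon receptor targets and erythroid cells, 1 rising for ATF4 targets and for the clock, 1 falling aryl hydrocarbon receptor target, and 0 falling clock and 0 rising oxidative phosphorylation and mitochondrial ribosomal genes. Leaving out GSK8573 library 2 gave 0 rising lipid synthesis, 0 falling clock and 0 rising oxidative phosphorylation genes, 1 falling cholesterol gene and 1 rising ATF4 target. Leaving out GSK8573 library 4 gave 1 rising and 2 falling p53 targets, 3 rising matrix genes, 2 rising oxidative phosphorylation and gallbladder genes, and 0 falling lipid synthesis and 0 rising mitochondrial ribosomal genes. By edgeR 0 genes of the proteasome (30, with 3 at unadjusted p under 0.05), YAP targets (19, with 3), fetal liver genes (10, with 4) and adipocyte markers (6, with 4) were called, against 0, 0, 1 and 4 by DESeq2 and 0 by limma-voom. With adjustment over the list alone, 1 adipocyte marker rose and 2 fell, while no proteasome, YAP or fetal liver gene passed. Lists with under 5 measured genes were not tested: neutrophils (3 measured, with Lcn2 lower), T and NK cells (2), B and plasma cells (4), pancreas (1) and mitochondrially encoded genes (0).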
